A study of Sus scrofa and Homo sapiens with 9 samples.

How the data were processed

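Droplet single-cell RNA libraries of liver non-parenchymal cells from minipigs were used, 1 each for oil, CCl4 in oil, and MGCD and AZA after fibrosis. Per the labels, biopsy or surgical liver tissue was digested with collagenase and dispase, strained, freed of red cells, spun at low speed to separate hepatocytes from the rest, made into gel-bead droplet libraries of polyadenylated RNA and sequenced on an Illumina NovaSeq. The authors deposited counts, whole numbers of UMIs per gene and barcode with no normalisation. The other deposited columns, read as labels and not as measurements, are cell barcodes, pig Ensembl gene IDs and gene symbols. Per the submitters' processing notes HISAT2 2.0.5 and the pig genome Sscrofa11.1 were used. The counting tool, annotation release and cell calling are not given in the sources used here. The series also lists 6 samples without files, 2 bulk pig and 4 bulk human, which were left out.

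Separate barcode lists were complete only for CCl4, with 4925 barcodes of which 4054 were among the kept cells, and what they select is not stated. The lists for oil and treated cells break off after 166 and 830 barcodes and were not used. Of 21390 genes, 6567 had no symbol, and they carried 25.6% of the oil UMIs. They stayed in the totals and in the clustering but are not named, apart from those with an unusual share of a library. The RefSeq table for Sscrofa11.1 gave coordinates of named genes, and 0 of the 6567 unnamed IDs could be matched to it.

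Barcodes with at least 500 UMIs and 200 genes were kept. The gene table has no mitochondrial genes, so no limit on mitochondrial content was applied. Doublets were called with Scrublet at an expected rate of 6%. It marked 0 of 15975 oil and 2 of 4068 CCl4 barcodes (0.049%), so it did not work there, and 424 of 8263 treated barcodes (5.13%), which were removed. This left 86.0%, 81.6% and 77.6% of the barcodes. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes and 30 principal components were taken, and the 3 libraries were clustered together by the Leiden method at resolution 1 with 15 neighbours and no correction between libraries. A cluster took a class name when at least 3 marker genes of a list written beforehand passed, each seen in at least 10% of its cells and at least 2-fold above the other cells. Class names are therefore written with the ending -like. Software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

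For each class with at least 50 cells in both libraries, UMIs were summed over cells and divided by the class total to give CPM. Genes with at least 50 UMIs over the libraries compared and 20 in the library with more were measured. Ratios carry 95% exact conditional binomial intervals, CPM exact Poisson intervals and shares Clopper-Pearson intervals. They cover counting error only, and no test or p-value was made from cells, since each group is 1 library. Calls by the rule of size are counted within gene lists and for the opposite direction, and describe these libraries only. A ratio against a library with 0 UMIs is given against a floor of 3 counts, and is not the lower end of an interval. Each gene list was written before the data were examined, as were the comparisons, the class markers, the filters and most alternatives. A list with at least 5 measured members is given by its called members, its median log2 ratio and the percentile of that median among 10000 random lists drawn from the same 20 bins of expression. The median log2 ratio of all measured genes was 0.19 and -0.19 in endothelial-like cells, 0.31 and -0.03 in macrophage-like cells and 0.30 and -0.18 in T and NK-like cells for the 2 comparisons, and median-ratio scaling was run as an alternative. The level in T and NK-like cells of the same library is given beside some genes of other cells, and it counts free RNA and doublets together.

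Named genes were picked by rule: the 10 largest ratios at each end with a symbol and an interval that excludes 2-fold, up to 4 called members of each list by UMIs or else 2 members, and all measured study targets. Ribosomal, mitochondrial, haemoglobin, immunoglobulin and hepatocyte-list genes were left out of the largest ratios, at most 1 gene at an end. The report prints part of this selection, and 1 gene and the list values that rest on it are not reported here. For the opposite direction, the CCl4 cells were divided at random 20 times. Genes were called against oil with 1 part, and the treated library was read against the other part. As a baseline the other part took the place of the treated library and was read against the part that called the genes. The genes that were neither higher nor lower were read in the same way.

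The endothelial comparison was tested once on simulated data drawn from the mean level of the 2 libraries with 200 genes altered, and 5710 genes had enough UMIs to be measured in it. Of 50 genes changed at each size, 47, 45, 40 and 39 were measured at 1.5-fold, 3-fold, 5-fold and 10-fold. The rule of size found 8.51% of those changed 1.5-fold and 100% at the larger sizes, and called 0.289% of unchanged genes. The simulated counts were Poisson draws with no differences between cells, clusters or animals, so these rates check the code and leave such differences out. The interval held the true ratio for 89.9% of unchanged genes with totals taken from the simulated counts and 95.6% with the totals that were simulated. For genes changed 10-fold these values were 84.6% and 92.3%. Of 40 random lists of unchanged genes 4 fell under percentile 5 and 2 over percentile 95. Alternatives covered the minimum UMIs per cell (1000), doublet removal, Leiden resolution (0.5 and 2), clustering of each library alone, listed barcodes, median-ratio scaling, totals without hepatocyte, haemoglobin and ribosomal genes or without 2 abundant unnamed genes, means of single cells, gene minimums of 20 and 200 UMIs, cells thinned to 1000 UMIs and the largest cluster of each class.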

Results

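Single-cell RNA was measured in the non-parenchymal cells of minipig liver, the cell suspension that keeps endothelial, immune, stellate and bile duct cells after most hepatocytes have been spun out. The question was how the vascular cells of a fibrotic liver differ from those of a control liver, and what they look like after drugs aimed at epigenetic enzymes. There were 3 droplet libraries and 1 library in each of 3 groups: oil, carbon tetrachloride in oil (CCl4, a toxin that scars the liver), and MGCD and AZA given after fibrosis. The oil library held 18565 barcodes with 29366802 counted molecules (UMIs), the CCl4 library 4983 with 5066780, and the treated library 10106 with 17117212. After filtering, 15975, 4066 and 7839 cells were kept, with medians of 1190, 866 and 1542 UMIs and 563, 509 and 710 genes per cell. The gene table listed 21390 genes, of which 6567 had no symbol. With 1 library per group there is no replicate check, so no test was made and every difference is a difference between these 3 libraries. Intervals are 95% and cover counting error only. The 6 further samples of the series, 2 bulk samples from pig and 4 from human liver, were not analysed here.

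Cells were grouped into 26 clusters and named by marker genes, and the balance of cell classes differed widely between the libraries. Endothelial-like cells were 22.8% (21.5 to 24.1) of the CCl4 cells, against 3.28% (3.01 to 3.57) in oil and 1.73% (1.46 to 2.05) in the treated library, which is 928, 524 and 136 cells. Macrophage-like cells, the liver's resident and recruited phagocytes, ran the other way at 42.7% (41.9 to 43.4) in oil, 8.53% (7.69 to 9.44) in CCl4 and 21.8% (20.9 to 22.7) in the treated library. With macrophages left out of the total, endothelial-like cells were still 5.72%, 25% and 2.22% of the rest. T and NK-like cells made up 34.7%, 53% and 47.1%, but 60.5%, 58% and 60.3% with macrophages left out. Cholangiocyte-like cells, which line bile ducts, were 0.444% in oil, 6.64% in CCl4 and 0.612% after treatment. Neutrophil-like cells were 2.45%, 1.84% and 18.2%, but they were 0% of oil and 7.34% of treated cells when each library was clustered alone. B-like cells were 4.79% in oil, 0.812% in CCl4 and 0.370% after treatment, and plasma-like cells 6.53%, 0.566% and 0.332%, but plasma-like cells were 0.664%, 1.11% and 0.791% when each library was clustered alone. Digestion, the spin and the depth of each library also set which cells are counted. A minimum of 1000 UMIs per cell took macrophages in oil from 42.7% to 20.5% and put T and NK cells at 51.0%, 41.4% and 58.6% of the 3 libraries, which reversed the order of oil and CCl4.

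**Figure D1:**
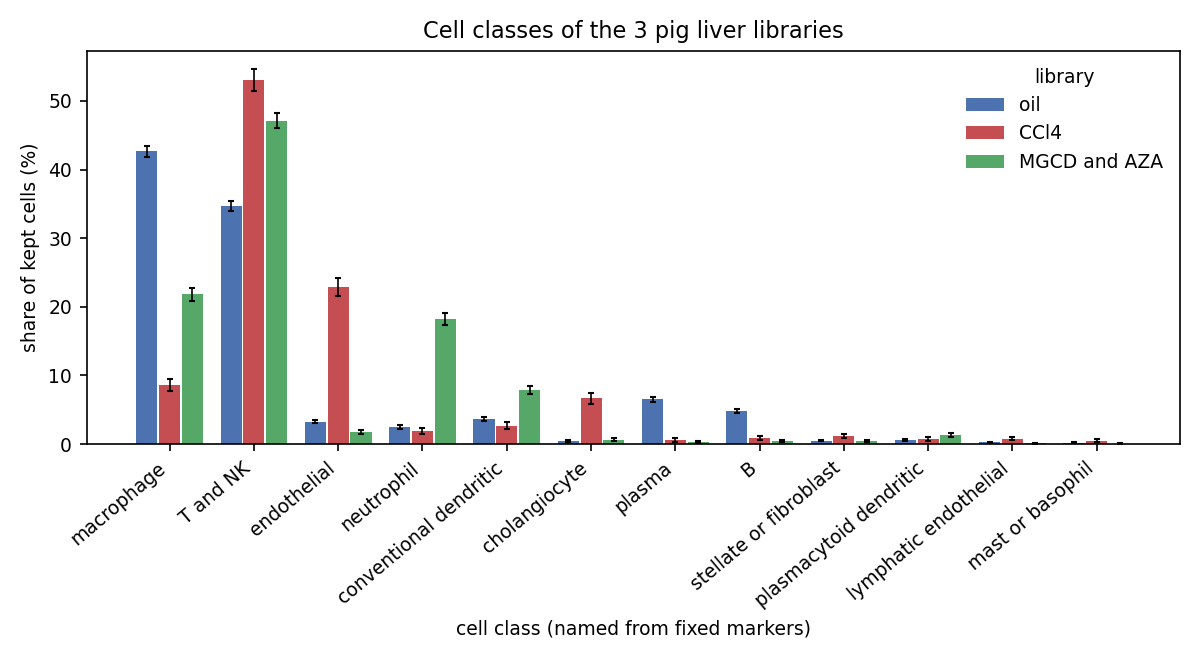
Share of kept cells in each cell class of the oil, CCl4 and MGCD and AZA libraries, with 95% exact binomial intervals for counting error; 1 library per group.

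In endothelial-like cells, CCl4 against oil, genes that mark the fenestrated sinusoidal lining of the liver were lower over the class as a whole. The list medians of continuous and arterial vessels, matrix proteins, the TGF-beta response and the interferon response were above 0, but only in the interferon list were most members higher within the main CCl4 cluster alone. A gene is called higher or lower here when its share of the UMIs of the class (given as CPM) differed at least 2-fold and the counting interval of the ratio left out 1. Each list of genes is given with the number of its members called, its median log2 ratio and the percentile of that median among 10000 random lists of similar expression. Of 9 measured sinusoidal genes 0 were higher and 8 lower (median -2.68, percentile 0.0). The lectin CLEC4G (ENSSSCG00000039007, chromosome 2, 71433406 to 71436570) was 38.2 times lower (28.7 to 52.1), at 43.2 CPM against 1652. The mannose receptor MRC1, which clears glycoproteins from blood, was 12.6 times lower (10.9 to 14.7), the alarm cytokine IL33 4.64 times (3.91 to 5.52) and the transcription factor MAF 6.40 times (5.23 to 7.89). In cells thinned to 500 UMIs, CLEC4G was seen in 40.6% of oil and 2.05% of CCl4 endothelial-like cells.

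The class was made of clusters 8 and 17, and the libraries drew on them in different proportions. Cluster 8, led by DEPP1, TMEM100, APOLD1 and GPIHBP1, held 897 of the CCl4 and 200 of the oil cells. Cluster 17, led by FCN2, CLEC4G, NELL2, OIT3 and EMILIN1, held 31 and 324. Within cluster 8 alone 2 sinusoidal genes were higher and 4 lower of 6 (median -1.29). MRC1 stood there at -1.30 and MAF at -1.29 on the log2 scale. Within cluster 17 alone 1 sinusoidal gene was higher and 1 lower of 9 (median 0.23). Continuous or capillary genes were 5 higher and 2 lower of 12 (median 0.85, percentile 98.5): the caveolar protein CAV1 was 3.92-fold higher (3.44 to 4.47) and CD34 2.17-fold, while PLVAP, the diaphragm protein of fenestrae, was 2.66 times lower and ENG 2.68 times. In cells thinned to 500 UMIs, PLVAP was also seen in 83.4% of oil macrophage-like cells. Without thinning, T and NK cells carried 410 CPM of it in oil and 59.6 in CCl4, against 1250 and 471 in endothelial-like cells. In cluster 8 alone 2 were higher and 1 lower (median 0.04), with CAV1 at 0.87, CD34 at 0.00 and ENG at -0.35. Arterial genes were 5 higher of 8 (median 1.36, percentile 99.8), including SEMA3G at 4.51-fold (3.58 to 5.74), GJA5 at 3.38 and the Notch ligand DLL4 at 2.81. In cluster 8 alone 2 of 8 were higher (median 0.63), where GJA5 stood at 0.66 and DLL4 at 0.80. Outside the lists, TMEM100, a target of BMP signalling in vessels, was 21.4-fold higher (16.4 to 28.2), and at 3.31 on the log2 scale in cluster 8, which it helps define. Among the largest other higher ratios outside the lists were the kinase brake SPRY1 at 12.5-fold (9.31 to 17.3) and the transcription factor GATA6 at 10.7 (4.4 to 33.9). The calcineurin inhibitor RCAN1 was at 10.5 (4.62 to 29.3) and the fatty acid carrier FABP4 at 10.2 (7.30 to 14.8).

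Signalling and response genes differed as well. Matrix genes were 5 higher and 0 lower of 9 (median 1.15, percentile 99.8), among them thrombospondin THBS1 at 10.8-fold (8.81 to 13.5), the protease inhibitor TIMP1 at 4.02 (3.34 to 4.89) and fibrillin FBN1 at 7.58 (3.68 to 18.1). In cluster 8 alone 3 of 8 matrix genes were higher (median 0.16). The TGF-beta response was 6 higher of 10 (median 1.05, percentile 99.7), with CCN1 at 3.57-fold, SKIL at 2.29 and SMAD7 at 2.04, but in cluster 8 alone only 1 of 9 was higher (median 0.82). Of 17 interferon-response genes 11 were higher and 0 lower (median 1.42, percentile 100), and within cluster 8 alone 12 of 16 were higher (median 1.73). ISG15, a ubiquitin-like protein, was 3.90-fold higher (3.37 to 4.52), IFIT1, which binds viral RNA, 3.8 (3.14 to 4.63) and MX2, an antiviral GTPase, 5.50 (4.09 to 7.54). Immediate-early genes, which also respond to tissue digestion, were 7 higher of 12 (median 1.93), with FOS at 5.37-fold and ZFP36 at 4.61. Of the paracrine factors of liver endothelium, CXCL12 was 3.06-fold higher (2.61 to 3.60) and ID1 2.47-fold, whereas WNT2, which patterns hepatocyte zones, was 13.4 times lower (6.73 to 30.3) and HGF 2.07 times. Activation genes were 4 higher of 9 (median 0.45), with IL6 at 5.98-fold and the adhesion protein VCAM1 at 3.04. Genes of other cells were lower in the CCl4 endothelial class: C1QA was 32.5 times lower, at 6821 CPM in oil endothelium, where T and NK cells of the same library carried 3032 CPM of it. CCL3L1 was 32.6 times lower (oil T and NK cells 3332 CPM) and the Kupffer list 0 higher and 4 lower of 5.

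**Figure D2:**
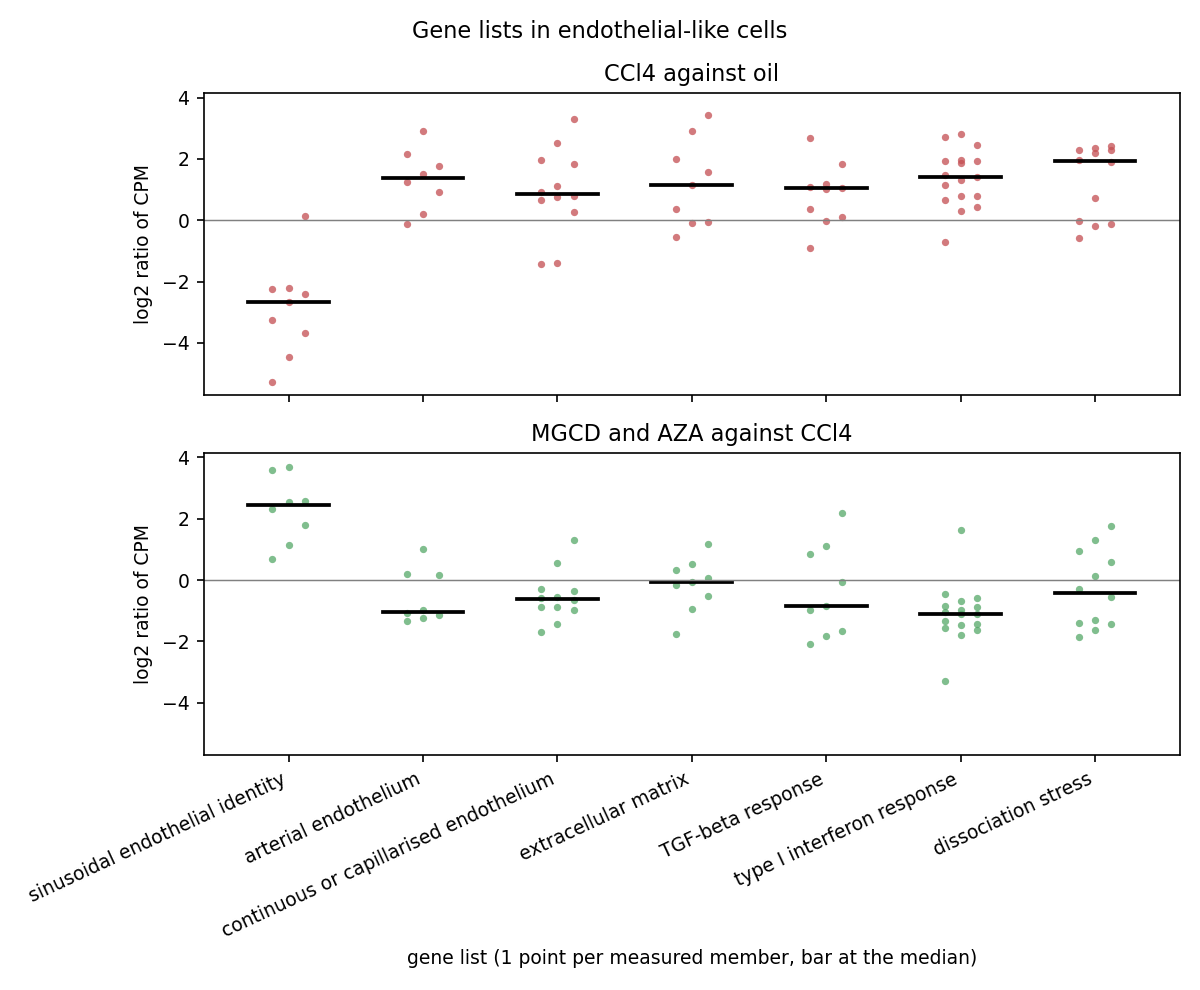
Log2 ratios of the measured members of the main gene lists in endothelial-like cells, CCl4 against oil and MGCD and AZA against CCl4, 1 point per gene with a bar at the list median.

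The enzymes that the drugs address and the vascular genes under study were read in the same endothelial-like cells. ADAMTS1 (ENSSSCG00000012026, chromosome 13, 190277175 to 190285957), a secreted protease that cleaves matrix proteoglycans, stood at 237 CPM (205 to 274) in oil, 1381 (1313 to 1452) in CCl4 and 820 (714 to 937) in the treated library. It was 5.82-fold higher in CCl4 than in oil (4.99 to 6.81), and 4.26-fold (3.53 to 5.18) within cluster 8. The treated value was 1.69 times lower than CCl4 (1.46 to 1.95), short of the 2-fold rule, which it passed with median-ratio scaling at -1.12 and with means of single cells at -1.54 on the log2 scale. Within cluster 8 the treated value was 1097 CPM against 1406, a ratio of 0.780 (0.667 to 0.907). The list of genes that also respond to tissue digestion took 0.730%, 2.54% and 1.18% of endothelial-like UMIs in oil, CCl4 and the treated library. That is the same order as ADAMTS1, and whether digestion set its level was not tested. IGFBP7 (ENSSSCG00000008913, chromosome 8, 56283089 to 56357822), a secreted binding protein made by vessels, stood at 661 CPM (605 to 721), 1105 (1044 to 1169) and 1115 (990 to 1250), which is 1.67-fold (1.51 to 1.86) and 1.01-fold (0.885 to 1.15). Nearly all of it came from cluster 8, where the values were 1425, 1130 and 1674 CPM and the first ratio turned to 0.793 (0.714 to 0.881); the second there was 1.48 (1.30 to 1.68). Among the epigenetic enzymes none passed the rule in either comparison as read here. HDAC2 (ENSSSCG00000004432, chromosome 1, 79867713 to 79901597) was 1.92-fold (1.36 to 2.74) in CCl4 against oil and 0.732-fold after treatment. On the log2 scale both HDAC2 values passed 2-fold with means of single cells, at 1.07 and -1.35, and in cluster 8 alone they were 0.54 and -0.23. HDAC1 (ENSSSCG00000003613, chromosome 6, 88749611 to 88785220) was 1.37-fold and 1.16-fold. The maintenance methyltransferase DNMT1 (ENSSSCG00000013659, chromosome 2, 68981564 to 69040364) was 0.523-fold (0.349 to 0.778) and 1.30-fold. On the log2 scale its first value passed the rule with median-ratio scaling at -1.04, and was -0.33 in cluster 8 alone. DNMT3A (ENSSSCG00000029413, chromosome 3, 113501972 to 113609148) was 1.07-fold and 0.851-fold. HDAC3 was 0.881-fold in CCl4, with too few UMIs to compare after treatment. HDAC11, UHRF1 and DNMT3B had too few in both comparisons, and HDAC8 was absent from the gene table.

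**Figure D3:**
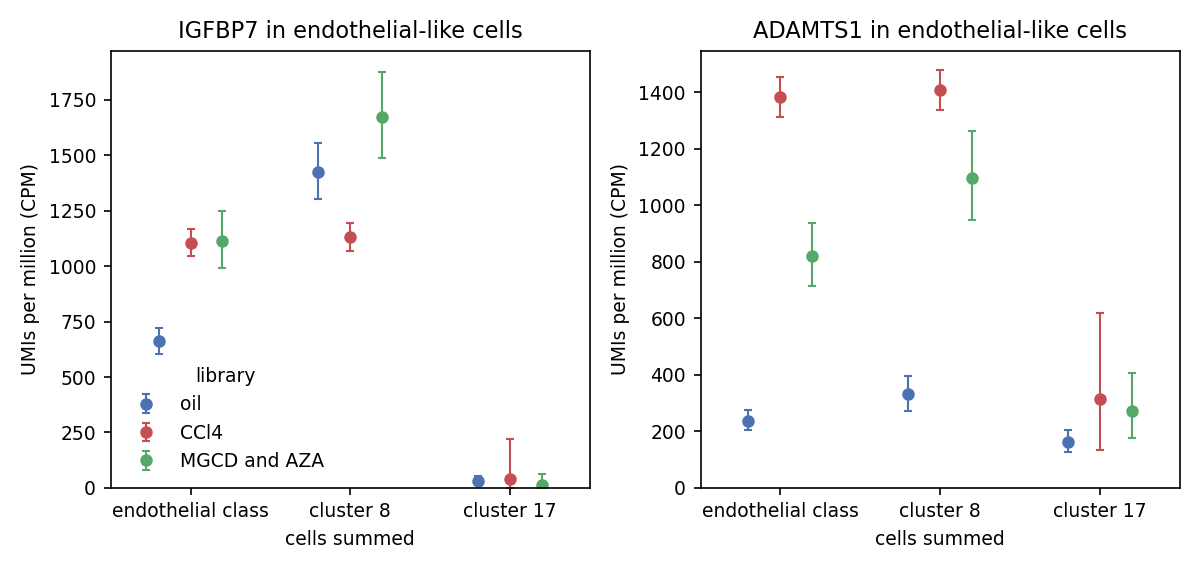
CPM of IGFBP7 and ADAMTS1 in endothelial-like cells of each library, for the whole class and for clusters 8 and 17, with 95% exact Poisson intervals; 1 library per group.

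In endothelial-like cells of the MGCD and AZA library against CCl4, most list medians had the opposite sign. Sinusoidal genes were higher and interferon-response genes lower, and the treated class held only 136 cells, of which 65 were in cluster 8 and 71 in cluster 17. Of 8 sinusoidal genes 7 were higher and 0 lower (median 2.43, percentile 100), with CLEC4G at 12.9-fold (9.22 to 18.2), MRC1 at 5.79 (4.81 to 6.98), the hyaluronan receptor LYVE1 at 3.45 (2.85 to 4.18) and the DNA-digesting enzyme DNASE1L3 at 6.01 (4.60 to 7.88). The sinusoidal median was 0.43 in cluster 8 alone, where DNASE1L3 turned to -0.61, and -0.22 in cluster 17 alone, with 0 higher and 1 lower of 7. Capillary genes were 1 higher and 2 lower of 12 (median -0.62, percentile 1.03): SPARCL1 was 2.72 times lower and the basement membrane collagen COL15A1 3.26 times. In cluster 8 alone 0 capillary genes were higher and 1 lower (median -0.15). Arterial genes were 1 higher and 4 lower of 8 (median -1.04, percentile 0.1). EFNB2 was 2.12 times lower, BMX 2.50 times and the Notch effector HEY1 2.36 times, but in cluster 8 alone 0 of 8 arterial genes were called (median -0.49), with EFNB2 at -0.55. Interferon-response genes were 1 higher and 10 lower of 17 (median -1.10, percentile 0.0), and 1 higher and 11 lower of 16 in cluster 8 alone (median -1.31). RSAD2, which makes an antiviral nucleotide, was 9.71 times lower (4.4 to 26.7), MX2 2.69 times (1.90 to 3.95) and IFIT1 2.51 times (1.94 to 3.30), while the chemokine CXCL10 was 3.07-fold higher (2.41 to 3.90).

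Other programmes were divided after treatment. Matrix genes were 1 higher and 1 lower of 9 (median -0.06), with TIMP1 2.24-fold higher and FBN1 3.37 times lower (1.49 to 9.43). The TGF-beta response was 2 higher and 3 lower of 9 (median -0.86), with TAGLN at 4.59-fold, SMAD7 3.13 times lower (1.85 to 5.70) and ACTA2 4.23 times lower (1.58 to 15.9). Means of single cells turned that median to 0.11 and ACTA2 to 0.75. In cluster 8 alone 3 TGF-beta response genes were higher and 2 lower of 9 (median -0.47). CXCL12 was 3.01 times lower (2.34 to 3.94), FOS 3.07 times and ZFP36 2.72 times. The chemokine CXCL8 was 8.78-fold higher (6.47 to 12), at 506 CPM against 57.6, where T and NK cells carried 103 and 70.7 CPM and neutrophil-like cells were 18.2% and 1.84% of the libraries. NFKBIA, the NF-kappaB inhibitor, was 2.79-fold higher (2.47 to 3.15). The largest named differences were THY1, a surface glycoprotein, at 23.0-fold (13.6 to 41.2), the decoy receptor IL13RA2 at 15.0 (9.68 to 23.9), and FCN2 at 13.8, EMILIN1 at 13.0, OIT3 at 12.1 and NELL2 at 12, the last 4 all genes that lead cluster 17. Lower genes were led by FAM13C at 25.6 times (7 to 213), on 2 treated UMIs, and CYP1A1, a xenobiotic-metabolising enzyme, at 11.7 times (5.30 to 32.0). CCL5 was 5.88-fold higher and CTSD 6.79-fold, with T and NK cells of the treated library at 25037 CPM of CCL5.

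Genes that differed in CCl4 were next asked for their direction after treatment, with the CCl4 cells split so that each comparison used different cells. Of the genes higher in CCl4 endothelial-like cells, 38.0% were lower in the treated library than in the other part of the CCl4 cells, and of the genes lower in CCl4, 52.6% were higher. Of the measured genes that were neither higher nor lower in CCl4, 10.3% were lower and 7.16% higher in the treated library. With the other CCl4 part in place of the treated library the values were 1.08% and 2.16%. This baseline was read against the part that picked the genes, so it holds the effect of picking as well as noise between cells. Both comparisons share the 1 CCl4 library, so whatever is particular to it also counts as an opposite direction. Within cluster 8 alone the values were 27.2% and 31.6%. Median-ratio scaling took the values of the class to 61.9% and 27.5%, and with the CCl4 library left undivided they were 41.4% and 59.6%. In macrophage-like cells 36.6% of the higher and 26.0% of the lower genes had the opposite direction after treatment, beside 9.07% lower and 4.19% higher of the genes that were neither, and 4.66% and 6.81% between CCl4 parts. With the CCl4 library undivided the macrophage values were 59.8% and 42.6%. In T and NK-like cells the values were 24.2% and 11.9%, beside 6.20% and 2.40% of the genes that were neither and 2.50% and 5.82% between CCl4 parts. Undivided they were 34.2% and 20.8%.

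In macrophage-like cells, CCl4 against oil, genes of the lipid-handling macrophages found in liver scars were far higher. Most oil cells came from cluster 1 (5413 of 6815) and most CCl4 cells from cluster 4 (225 of 347), so the values compare different clusters. Among genes with a symbol, C1QA, CCL14 and C4BPA led cluster 1, and MARCO, ACP5 and GPNMB led cluster 4. The first leading gene of cluster 1 has no symbol. It was at least 20-fold lower in CCl4 than in oil in endothelial, macrophage and T and NK-like cells alike. Clustering was not corrected between libraries, so distinct populations and a difference between whole libraries cannot be told apart here. All 9 scar-associated genes were higher (median 3.34, percentile 100). The bone matrix protein SPP1 (ENSSSCG00000009216, chromosome 8, 131077786 to 131085334) was 70.8-fold higher (54.9 to 92.4), lipoprotein lipase LPL 87.9-fold (42.5 to 204), apolipoprotein APOE 18.0 (16.6 to 19.5), LGALS3 12 and the lysosomal glycoprotein GPNMB 10.1 (9.42 to 10.8). Interferon-response genes were 12 higher and 0 lower of 17 (median 1.52, percentile 100), with MX2 at 6.78-fold (5.74 to 7.99), IFIT1 at 3.42 and OAS2 at 2.88. Of 7 resident Kupffer genes, the scavenger receptor MARCO was 12.3-fold higher (10.8 to 14.0) and TIMD4, which binds dying cells, 2.21 times lower (1.91 to 2.58). Antigen presentation by MHC class II was 1 higher of 7 (median 0.62), HLA-DRA at 2.06-fold. Hypoxia genes were 4 higher of 7 (median 1.20) with VEGFA at 5.65-fold, but that median turned to -0.43 and VEGFA to -1.77 when each library was clustered alone. Activation genes were 5 higher and 1 lower of 9 (median 1.18), among them CXCL8 at 29.7-fold, CXCL2 at 11.6 and CCL2 at 3.48. At clustering resolution 2 their median turned to -1.07, and CXCL8, CXCL2 and CCL2 each turned lower as well. The list median and CCL2 also turned when each library was clustered alone. RNF128, a ubiquitin ligase, had the largest ratio at 155-fold (70.9 to 401), and RARRES1 was 91.2-fold and the lipid mediator hydrolase PLA2G7 52.5-fold. TPM2 was 95.1 times lower (37.1 to 349).

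In macrophage-like cells of the treated library against CCl4, cluster 4 held 1643 of 1710 treated cells, and the CCl4 cells also held 109 of the inflammatory cluster 16. Inflammatory cytokines were 0 higher and 9 lower of 11 (median -1.69, percentile 0.0), with TNF 3.45 times lower (2.98 to 3.99) and CXCL8 6.71 times (5.82 to 7.74). This result reversed to 1.96 within cluster 4 alone, where CXCL8 was at 4.38, and to 0.92 when each library was clustered alone, where TNF was at 2.03. Interferon-response genes were 0 higher and 8 lower of 16 (median -0.95, percentile 0.0500): CXCL10 was 4.42 times lower (3.73 to 5.23), MX2 3.21 times (2.69 to 3.82) and OAS2 2.45 times (1.87 to 3.18). MHC class II genes were 0 higher and 3 lower of 5 (median -1.48), with HLA-DRA 3.17 times lower (3.02 to 3.32), SLA-DQB1 3.12 times and the invariant chain CD74 2.78 times, but in cluster 4 alone 0 of 5 were called (median -0.52), with HLA-DRA at -0.87. Of the scar-associated genes 1 was higher and 2 lower of 9 (median -0.62): the protease CTSD was 2.31-fold higher (2.20 to 2.42), the lipid carrier FABP5 2.53 times lower and LPL 3.88 times. The Kupffer genes CD163 and TIMD4 were 2.13-fold and 2.83-fold higher, and CLEC4F, a lectin of resident Kupffer cells, was 7.59-fold higher (6.28 to 9.26). The monocyte-attracting chemokine CCL2 was 171 times lower (56.6 to 843), lysozyme LYZ 72.4 times (31.8 to 203) and complement C3 12.5 times (7.94 to 20.1). These 3 had too few UMIs to compare in cluster 4 alone, and at clustering resolution 2 a monocyte cluster with LYZ and FCN1 among its leading genes took 155 CCl4 and 60 treated cells. HDAC1 was 2.42 times lower (1.65 to 3.49) and DNMT3A 2.39 times (1.29 to 4.24), the only study targets past the rule in this comparison, but HDAC1 was at -0.47 on the log2 scale in cluster 4 alone.

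In T and NK-like cells, CCl4 against oil, most interferon-response genes were higher. Of 17 genes 12 were higher and 0 lower (median 1.22, percentile 100), with MX2 at 9.62-fold (7.53 to 12.4), HERC5 at 9.41 (7.09 to 12.6), MX1 (ENSSSCG00000012077) at 7.92 (5.49 to 11.5) and RSAD2 at 6.35 (5.18 to 7.81). The cytokine receptor IL23R was 3.54-fold higher (2.42 to 5.14) and the ligand sensor AHR 3.79-fold (2.71 to 5.27). IL17A had 35 UMIs in 8 of 2157 CCl4 cells and 0 in 5542 oil and 3694 treated cells, too few to compare. The class was drawn from different clusters: cluster 7, led by XCL1 and with GNLY among its markers, held 24.1% of oil and 2.23% of CCl4 cells. Inhibitory receptors of exhausted T cells were 3 higher of 7 (median 0.67): HAVCR2 8.91-fold (6.27 to 12.8), CTLA4 2.55 and PDCD1 2.28. Cytotoxic genes were 0 higher and 2 lower of 12 (median -0.20), with granulysin GNLY 5.16 times lower (4.94 to 5.39) and the chemokine CCL5 2.23 times. Within cluster 3 alone GNLY was at -2.07 and CCL5 at -1.32 on the log2 scale. FCER1A was 14.0-fold higher (8.34 to 24.3) and the homing receptor CCR2 6.99 (5.10 to 9.63). FCER1A is also among the leading genes of dendritic cluster 22 and mast or basophil-like cluster 26, and whether free RNA or doublets raised it was not tested. The genes lower by most, such as CLEC4F at 22.3 times and CCL14 at 20.4 times, stood at 1954 and 1790 CPM in oil macrophage-like cells, and free RNA was not separated from doublets.

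In T and NK-like cells of the treated library against CCl4, interferon-response genes were 0 higher and 11 lower of 17 (median -1.38, percentile 0.0). MX2 was 10.5 times lower (7.98 to 14.0), CXCL10 7.12 times (4.79 to 10.7), USP18, which ends interferon signalling, 2.80 times and RSAD2 2.61 times. Killing genes ran the other way: 4 higher and 0 lower of 12 (median 0.62, percentile 99.9), with GNLY at 6.29-fold (6.02 to 6.58), the granzymes GZMK at 3.29 (2.97 to 3.66) and GZMA (ENSSSCG00000016903) at 2.95 (2.81 to 3.09), and CCL5 at 3.23. Cluster 5, led by LAG3, GZMB, CRTAM and PDCD1, held 37.9% of treated, 5.10% of CCl4 and 1.41% of oil cells of the class, so these values compare different mixes of clusters. Within cluster 2 alone the cytotoxic list was 5 higher and 0 lower of 12 (median 0.31), with GNLY at 4.01 and GZMK at 1.44 on the log2 scale. Exhaustion genes were 1 higher of 7 (median 0.54, percentile 99.9), the inhibitory receptor LAG3 at 2.51-fold (2 to 3.18). AHR was 3.94 times lower (2.75 to 5.62), IL23R 2.09 times (1.46 to 2.97), and the epithelial repair cytokine IL22 5.34-fold higher (1.75 to 26.6). Inflammatory cytokines were 3 higher of 7 (median 0.98), CCL3L1 at 4.33-fold (4.10 to 4.57) and CXCL2 at 4.51. CXCL2 is among the leading genes of neutrophil-like cluster 10. Neutrophil-like cells were 18.2% of treated and 1.84% of CCl4 cells, and free RNA was not tested here. FCER1A, also among the leading genes of dendritic cluster 22, was 13.4 times lower (7.65 to 24.5). The histone deacetylase HDAC9 was 6.31 times lower (3.8 to 10.6) and RHEX 5.94 times (4.97 to 7.12). LIN7A had 0 UMIs in CCl4 and was 12.1-fold higher after treatment when set against the floor of 3 counts.

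**Figure D4:**
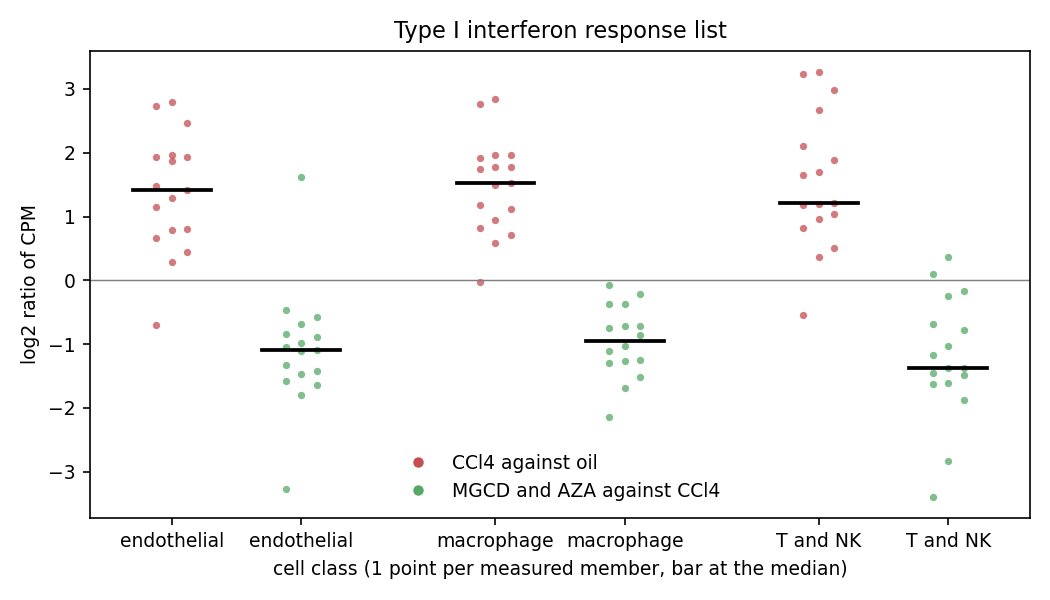
Log2 ratios of the measured interferon-response genes in the 3 cell classes, CCl4 against oil and MGCD and AZA against CCl4, with a bar at each median.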

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

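Both points below were chosen only after the result was seen, as genes without a name that took an unusual share of a library and lay outside the planned comparisons.

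In the CCl4 library the unnamed gene ENSSSCG00000032207 took 5.32% of all UMIs in kept cells, against 1.67% in the oil control and 0.00313% in the treated library, where it had 480 UMIs. A single gene rarely takes that much of a library, and it has no symbol in the gene table, so no gene list and no named comparison included it. It was spread over the classes of CCl4 cells with at least 50 cells, among them 5.24% of UMIs in endothelial-like, 5.21% in macrophage-like, 6.38% in T and NK-like, 3.75% in neutrophil-like, 2.40% in dendritic and 4.13% in cholangiocyte-like cells. Among the classes of that size the highest was 2.66 times the lowest, so no kept cell class stood out as the source. Free RNA also spreads over all classes, and the bounds were set after the result was seen, so free RNA was not excluded. Free RNA from lysed hepatocytes stayed open by the test set for it: the treated library had 5.91 times less of the hepatocyte genes than CCl4, between the bounds of 10 and 2, while the unnamed gene was 1703 times lower. The hepatocyte genes took 0.359% of UMIs in CCl4 and 0.140% in oil, but 11765 of their 16750 CCl4 UMIs lay in cholangiocyte-like cells. In T and NK-like cells they were lower in CCl4 than in oil (0.0449% against 0.114%), as in macrophage-like cells (0.0398% against 0.216%), where the unnamed gene was higher. The treated library had 0.0407% of hepatocyte genes in macrophage-like cells, close to CCl4. In endothelial-like cells they took 0.325% in CCl4 and 0.312% in the treated library, but in T and NK-like cells the treated value was lower, at 0.0228%. The unnamed gene took 0.00375%, 0.00498% and 0.00292% in these 3 treated classes. Other sources, such as an abundant noncoding RNA, a difference between animals at this locus or a step of library making, were not tested.

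A further unnamed gene, ENSSSCG00000035520, took 3.22% of UMIs in CCl4, against 0.951% in oil and 0.2% in the treated library. It too stood above the oil control and outside every gene list. Its source was not tested. Leaving both genes out of the totals moved the T and NK interferon median after treatment to -1.54.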

How the results depend on the processing

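The class shares printed in the text and the 2 planned comparisons in endothelial, macrophage and T and NK-like cells were computed again under alternatives. These were chosen before the data were examined, except 2 chosen after: keeping only cells with a doublet score under 0.25, and totals without the 2 abundant genes that have no name. A value is called moved when it left the counting interval of its own result, and reversed when a called gene or a list changed sign. The 6 list medians counted among the leading results were picked after their values were seen, and the macrophage cytokine median was kept among them although it reversed. No paired analysis was possible because each group has 1 library, and the numbered bulk samples have no file here. The alternatives for mitochondrial content were not run, since the gene table has no mitochondrial genes. The listed-barcode alternative was run for CCl4 only, because the other 2 lists break off. The largest-cluster alternative gives no macrophage value for CCl4 against oil, where cluster 1 held 9 CCl4 cells. The comparisons of treated cells with oil and those of other classes were not computed again, apart from values within single endothelial clusters. Of 370 named gene calls, 210 kept the rule under every alternative in which the gene was measured, and the largest-cluster alternative measured only 217. Unless a reason is given with a value, the cause was not tested.

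A minimum of 1000 UMIs per cell moved 10 of 12 shares of the 4 main classes, and this follows from its construction, since it drops cell types with little RNA. Endothelial-like cells became 26.3% of CCl4 and 1.29% of treated cells, macrophages 20.5% of oil, 7.53% of CCl4 and 15.2% of treated cells, T and NK cells 51.0%, 41.4% and 58.6%, and neutrophils 2.79% of CCl4 and 12.2% of treated cells. Cholangiocyte-like cells became 10.9% of CCl4 cells. The sinusoidal median in endothelium moved to -3.46 for CCl4 against oil and the scar-associated median in macrophages to 2.94. The macrophage stress list in CCl4 turned to -0.0240, and 44.9% of endothelial genes lower in CCl4 were higher after treatment. Of 335 gene calls 302 kept the rule.

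Leaving doublets in gave macrophages 20.8% of treated cells and neutrophils 1.37% of oil and 1.33% of CCl4 cells. The macrophage scar-associated median became 3.51 and the cytokine median after treatment -1.91. In T and NK cells after treatment the scar-associated median turned to 0.0373 and MARCO to 0.29. The doublet score under 0.25 gave 44.9% macrophages and 33.2% T and NK cells in oil, and 58.6% of the endothelial genes lower in CCl4 were higher after treatment.

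Clustering at resolution 0.5 put neutrophils at 3.27% of oil and 3.59% of CCl4 cells, the macrophage scar-associated median at 3.5 and the cytokine median at -1.88. It left 0% plasma-like cells in any library and put B-like cells at 11.3% of oil, 1.92% of CCl4 and 1.16% of treated cells. Resolution 2 gave macrophages 6.62% of CCl4 cells and neutrophils 0.983%, 1.08% and 16.3% of oil, CCl4 and treated cells. There the scar-associated median was 2.68 and the macrophage cytokine median after treatment -0.0224. In macrophages, CCl4 against oil, CCL2 turned to -3.64, CXCL2 to -0.94, CXCL8 to -3.04, the activation list to -1.07 and the cell cycle list to -0.49. In the treated library against CCl4, CXCL2 turned to 3.51, CXCL8 to 5.10 and the activation list to 0.0496, and the T and NK cell cycle list to 0.10.

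With each library clustered alone, macrophages were 7.35% of CCl4 cells and neutrophils 0% of oil, 1.30% of CCl4 and 7.34% of treated cells. B-like cells were 8.55%, 0% and 0%, plasma-like cells 0.664%, 1.11% and 0.791% and cholangiocyte-like cells 0.532%, 4.30% and 0.255%. The macrophage scar-associated median was 2.58, the T and NK interferon median after treatment -1.02, and 57.1% of endothelial genes lower in CCl4 were higher after treatment. In macrophages, CCl4 against oil, these turned: BTG2 to -0.57, CCL2 to -2.33, DUSP1 to -1.03, FOS to -1.38, KLRK1 to 0.17, NDRG1 to -0.43, PMAIP1 to -0.24, SKIL to -0.00401 and VEGFA to -1.77. So did the cytotoxic list to 0.81, the stress list to -1.03, the activation list to -1.91 and the hypoxia list to -0.43. In treated macrophages against CCl4 the cytokine median reversed to 0.92, with CCL3L1 at 4.22, CCL4 at 1.47, CXCL2 at 1.66 and TNF at 2.03. DUSP1 turned to 1.29, FOS to 0.51, ICAM1 to 2.10, KLRK1 to -0.32, NFKBIA to 1.44, VEGFA to 1.67 and ZFP36 to 0.78. Their lists turned as well: cytotoxic -0.13, stress 0.56, activation 1.03 and hypoxia 0.81. In T and NK cells, CCl4 against oil, DNASE1L3 turned to 0.83, the scar-associated list to -0.0173 and the sinusoidal list to 0.19. Of 352 gene calls 291 kept the rule.

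Using only the largest cluster of a class removes the mix of clusters by construction. In endothelium the sinusoidal median became -1.29 for CCl4 against oil and 0.43 after treatment, the angiocrine list turned to -0.11 for CCl4 against oil, and after treatment the stress list turned to 0.0860 and DNASE1L3 to -0.61. Of the endothelial genes higher in CCl4 27.2% were lower after treatment there, and of those lower 31.6% were higher. In treated macrophages against CCl4 the cytokine median reversed to 1.96 and the activation list turned to 1.23, with CCL3L1 at 2.21, CCL4 at 0.77, CXCL2 at 1.96, CXCL8 at 4.38, ICAM1 at 1.26 and NFKBIA at 0.0681. The T and NK interferon median was 1.47 in CCl4 against oil and -0.86 after treatment, and IL10 turned to -0.40 in CCl4. Of 217 gene calls 146 kept the rule.

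Median-ratio scaling put the sinusoidal median after treatment at 2.06, the macrophage scar-associated median at 3.03 and the T and NK interferon median in CCl4 at 0.80. Of the endothelial genes higher in CCl4, 61.9% were lower after treatment, and of those lower 27.5% were higher, which follows from a shift of every ratio in the same direction. In T and NK cells the class I list turned to -0.0697 and the stress list to -0.17 in CCl4, and after treatment the HDAC inhibitor list turned to 0.0710 and the p53 list to 0.000735. The macrophage stress list in CCl4 turned to -0.14. Totals without hepatocyte, haemoglobin and ribosomal genes put the T and NK interferon median in CCl4 at 1.09. Totals without the 2 abundant unnamed genes put it at -1.54 after treatment and the endothelial genes with the opposite direction at 44.2% of those higher in CCl4. Means of single cells put the macrophage cytokine median at -1.90, and turned ACTA2 to 0.75 and the TGF-beta list to 0.11 in treated endothelium.

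A gene minimum of 20 UMIs put the sinusoidal median after treatment at 2.06, turned the endothelial angiocrine list in CCl4 to -0.37 and the T and NK p53 list after treatment to 0.0432, and gave 33.8% and 42.3% of endothelial genes with the opposite direction. A minimum of 200 UMIs gave a scar-associated median of 2.77, a T and NK interferon median after treatment of -0.86 and 63.4% of the endothelial genes lower in CCl4. List members with at least 20 UMIs in each library gave 2.77 for the scar-associated list, and 0.39 for the TGF-beta list in treated endothelium, which turned. Cells thinned to 1000 UMIs gave a sinusoidal median of -3.20 in CCl4, a scar-associated median of 2.74, a macrophage cytokine median of -2.81, a T and NK interferon median after treatment of -1.02 and a p53 list there that turned to 0.0804. Thinning left out 523 endothelial, 231 macrophage and 1520 T and NK cells of CCl4. The listed barcodes of CCl4 moved none of 12 shares and kept 369 of 370 gene calls. Median-ratio scaling kept 325 of 370 gene calls, and single-cell means 340.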

Other observations

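Treated macrophage-like cells differed widely from those in oil. Scar-associated genes were 8 higher and 0 lower of 9 (median 2.41), with SPP1 at 132-fold (105 to 168), LPL at 22.6, APOE at 10.9 and LGALS3 at 9.44. Genes of cell division were 8 higher and 0 lower of 12 (median 1.51, percentile 100), among them TOP2A, which untangles DNA, at 4.47-fold, UBE2C at 6.53 and CENPF at 5.20. Cluster 4 held 96.1% of treated and 0.249% of oil macrophage-like cells, and cluster 1 held 0.175% and 79.4%, so the libraries shared almost no cluster here. T and NK-like cells of the treated library carried more inhibitory receptors than those of oil, 6 higher and 0 lower of 7 (median 1.25, percentile 100), with HAVCR2 at 14.4-fold, LAG3 at 3.49, PDCD1 at 3.31 and TIGIT at 2.03. Cluster 5, led by LAG3 and with PDCD1 among its leading genes, held 37.9% of the treated and 1.41% of the oil cells of this class, so different mixes of clusters were compared. Their cytotoxic list was 5 higher and 0 lower of 12 (median 0.63), with PRF1, which opens pores in target cells, at 2.76-fold and GZMK at 2.74, while cell cycle genes were 0 higher and 4 lower of 14 (median -0.63). In treated endothelial-like cells 1 sinusoidal gene was higher and 4 lower of 9 against oil (median -0.95), with CLEC4G 2.97 times lower and MRC1 2.18 times. Cluster 17 held 61.8% of oil, 3.34% of CCl4 and 52.2% of treated endothelial-like cells. Within cluster 8 alone 1 was higher and 3 lower of 5 (median -1.32, beside -1.29 for CCl4 against oil), and within cluster 17 the treated median was -0.28. Their activation genes were 6 higher and 0 lower of 8 against oil (median 1.61, percentile 100), including IL6 at 10.7-fold and CXCL8 at 8.08. These comparisons with oil were read after the planned ones, and of the alternatives only the values within single endothelial clusters were computed for them.

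Other classes were compared where both libraries had enough cells. In conventional dendritic cells the interferon list was 10 higher and 0 lower of 11 in CCl4 against oil (median 1.75) and 0 higher and 8 lower of 10 in the treated library against CCl4 (median -1.38). These cells also sat in different clusters: cluster 22 held 22.2% of oil, 51.9% of CCl4 and 2.60% of treated cells, and cluster 12 held 48.6%, 30.6% and 84.1%. Neutrophil-like cells of the treated library against oil were 7 higher and 0 lower of 10 for inflammatory cytokines (median 1.71, percentile 99.9), with CXCL8 at 7.99-fold and NLRP3, which assembles the inflammasome, at 3.61. They were 12 higher and 1 lower of 17 for interferon genes (median 1.65), with ISG15 at 8.43-fold and CXCL10 13.5 times lower, and 0 higher and 6 lower of 6 for MHC class II (median -1.80), HLA-DRA 4.33 times lower. Which cells form this class in oil depends on the clustering: at resolution 2 a monocyte cluster with LYZ and FCN1 among its leading genes took 334 oil cells, and neutrophil-like cells were 0.983% of oil, and 0% with each library clustered alone. Cholangiocyte-like cells in CCl4 against oil carried more hepatocyte RNA, 6 higher and 0 lower of 12 (median 1.08). Ribosomal protein genes in endothelial-like cells were 2 higher and 34 lower of 55 in CCl4 against oil (median -1.11) and 22 higher and 0 lower of 54 after treatment (median 0.84). Smaller lists in endothelial-like cells, CCl4 against oil, gave 1 higher and 0 lower of 6 for MHC class I, 0 higher and 1 lower of 7 for class II, 2 higher and 2 lower of 6 for hypoxia, 1 higher and 0 lower of 5 for HDAC inhibitor response (CLU at 3.02-fold) and 2 higher and 0 lower of 7 for the p53 response (GADD45A at 4.01). Notch genes were 3 higher and 0 lower of 4 there, with HEY1 at 7.46-fold and JAG1 at 5.91, and 0 higher and 2 lower of 4 after treatment. Regulatory T genes in T and NK-like cells were 2 higher and 0 lower of 4 in CCl4 and 0 higher and 1 lower of 4 after treatment. Of 6 germline genes silenced by DNA methylation 0 were measured in any of the 3 classes, so their response to the drugs could not be read, and of the erythroid genes 1 was measured.

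The 5 tests of the next 2 patterns were written before their values were computed. The lower sinusoidal list of CCl4 endothelial-like cells was weighed against 3 explanations. For free RNA, the members lower in CCl4 had a median T and NK level in oil of 0.00568 of the endothelial level, where 0.5 or more was needed. Free RNA at the level of T and NK cells would thus supply little of their oil level. The test could not exclude free RNA in general, since members such as CLEC4G and OIT3 also helped to name the class, which made a high ratio unlikely. The test of cell depth gave a median of -3.20 with every cell thinned to 1000 UMIs. It could not decide, since a ratio of summed UMIs hardly depends on the depth of each cell. Thinning also left out 523 CCl4 and 220 oil cells. At 500 UMIs per cell, with none left out, CLEC4G was seen in 40.6% of oil and 2.05% of CCl4 cells. MRC1 was seen in 49.2% and 8.62%, but LYVE1 in 8.97% and 10.8%. Another mix of the 2 endothelial clusters was left open: the list median was -1.29 in cluster 8 and 0.225 in cluster 17, which held only 31 CCl4 cells. Members went both ways, with 2 higher and 4 lower of 6 in cluster 8 and 1 higher and 1 lower of 9 in cluster 17. The clusters were drawn from genes that include the list members. Loss of sinusoidal identity in each cell and loss of sinusoidal cells from the suspension therefore cannot be told apart.

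The interferon list, higher in CCl4 than in oil and lower again after treatment in all 3 classes, was weighed against 2 explanations. Scaling of the libraries was excluded, since with median-ratio scaling the smallest of the 6 absolute list medians was 0.798 and none changed sign. For free RNA from 1 class, the highest class share of these UMIs in CCl4 was 2.22 times the lowest, so none of the 3 classes stood out. The test could not exclude free RNA, which spreads over all classes and may come from a class outside these 3. An infection or immune state of single animals was not tested and would need more animals per group.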
